A study of Mus musculus with 6 samples.

How the data were processed

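RNA was measured in cells named long-term hematopoietic stem cells (LT-HSCs), per the labels from 6 mice. LT-HSCs are the rare bone marrow cells that renew the blood for life. The labels call the cells hematopoietic stem and progenitor cells, and the name LT-HSC comes from the series description and the deposited table. Per the labels, 3 mice were wild type (replicates 1 to 3) and 3 carried a conditional knockout of Mel18 in the blood system (replicates 4 to 6). Mel18 is the protein of the gene Pcgf2, a subunit of polycomb repressive complex 1. Per the labels' protocols, cDNA was made with the SMART-Seq v4 ultra low input kit and libraries with Nextera XT, a combination that does not mark strand. The marker gate of the sort, whether cells of several mice were pooled, the age and the sex of the mice, and the exons removed are not given in the sources used here.

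The authors deposited a single table of 13935 genes. It holds raw counts per gene and library, log2 FPKM values, the summed exon length of each gene, and their own comparison with fold changes, log2 fold changes, p-values and adjusted p-values. Its header names that comparison Cre+ LT-HSC against Cre- LT-HSC. Where Cre+ stands for the knockout libraries, an effect of Cre, a recombinase, cannot be told apart from that of the genotype. Per the submitters' processing notes, FastQC, MultiQC 0.11.5, Trimmomatic 0.40, STAR 2.5 and edgeR 3.28.1 were used with the mouse build mm10. The name of the authors' deposited table adds featureCounts, a counter of reads per gene. Its strand setting, the treatment of reads mapping to several genes and the rule for keeping genes are not given in the sources used here. Of the 13935 genes, 109 had 0 counts in all 6 libraries, and 0 mitochondrially encoded and 0 hemoglobin genes were listed. The deposited counts were used for every comparison here. The authors' log2 FPKM values served only to compare each library's total, and their deposited fold changes and p-values are quoted once, as theirs. The total implied by the log2 FPKM values that the authors deposited exceeded the listed counts, which made up 91.6% to 99.7% of it.

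Counts per library summed to between 26469336 and 37180701, so that 3 counts correspond to 0.0807 to 0.113 CPM (counts scaled to a common library size). Intervals and floors based on counts cover counting error only, since these reads carry no molecular identifiers. Gene symbols were compared with GENCODE release M21, which uses the same build: 96.2% of symbols matched, and 99.9% of the matched genes overlapped the annotated position. For 7 members of the gene lists the table used an older symbol, found through synonyms.

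Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its minimum of 10 counts, which left 12603, and libraries were scaled by TMM factors, which lay between 0.949 and 1.042. Genotype was tested with edgeR's quasi-likelihood test with robust estimation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. List medians with genes at 0 in a group set to their bound were the same to 2 decimals. Fixed gene lists with at least 5 tested members were tested with camera in limma on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 37 lists, and again with an estimated correlation and with fry. Fitted fold changes of genes at 0 in a group depend on the prior count. For such genes a bound is given against a floor of 3 counts over the group, and for genes with 1 to 3 counts the ratio of counts per effective library size with a 95% exact binomial interval.

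The design, the alternatives, 41 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes Pcgf2, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean log2 CPM is at least 1, leaving out Gm- and Rik-named models, pseudogenes and sex-linked genes. It adds up to 4 called members of each list or else the 2 with the smallest p, and 25 fixed genes. A gene outside this rule is said to have been chosen after its values were seen. The sex-linked list served as a check of the samples, and 3 lists had under 5 tested members: polycomb-bound developmental regulators (3), nuclear-retained non-coding RNAs (4) and mitochondrially encoded genes (0). Replicate numbers are not shared between the groups, so no pairing was modelled.

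The alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, edgeR's likelihood ratio and exact tests, a test against a fold of 1.5, other scaling factors, other count filters, other thresholds, removal of the 20 most abundant genes and leaving out each library in turn. Thinning all libraries to the shallowest total and removing each library's trend on exon length (a loess curve with a span of 0.5, used as an offset in edgeR and subtracted from log2 CPM for camera) were added after seeing the data. The scripts were tested on simulated counts with the means and spread of these libraries. Of 50 genes changed by each fold, the test called 6% at 2-fold, 40% at 4-fold, 70% at 8-fold and 68% at 16-fold, among 12194 genes, with 7 calls among unchanged genes. Changes of a few fold therefore often go uncalled with these libraries.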

Results

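The study asked whether loss of the polycomb protein Mel18 alters transcription in mouse LT-HSCs. By their labels, the libraries came from 3 wild-type mice and 3 Mel18 knockout mice. Total counts were 30087057, 26469336 and 30950057 in wild-type replicates 1 to 3. They were 37180701, 36825275 and 33537679 in knockout replicates 4 to 6. Between 12150 and 12981 genes had counts in a library.

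Pcgf2, the gene of Mel18 (mm10 chromosome 11, 97688823 to 97700497, minus strand), was not lower in the libraries labelled knockout. It had 43, 68 and 54 counts in the wild-type libraries and 72, 72 and 107 counts in the libraries labelled knockout. The means were 1.93 ± 0.60 and 2.37 ± 0.86 CPM (SD, n = 3 each). The log2 fold change was 0.30 (SE 1.14), with an adjusted p = 0.952 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and -0.04 without knockout replicate 6. Counts over the whole gene do not show whether the deleted exons are still transcribed. Because this check does not separate the groups, every direction below is between libraries by their labels. Pairs of means give the wild-type libraries first, each with its SD over libraries (n = 3). The labels give 1 mouse per library, but 3 libraries held both Xist and Y-linked transcripts, and whether cells of several mice were pooled is not given in the sources used here.

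Knockout replicate 6 lay apart from the other 5 libraries. On the first principal component of log2 CPM (39.0% of the variance) it scored 167 and the others between -71.6 and 7.75. The second component (25.2%) set knockout replicates 4 and 5, at -103 and -75.1, apart from the wild-type libraries, which scored between 29.4 and 63.6, and placed knockout replicate 6, at 48.5, within the wild-type range. Correlations of log2 CPM across genes were 0.880 to 0.887 between wild-type libraries and 0.876 between knockout replicates 4 and 5, against 0.802 and 0.813 for replicate 6 with these. The labels of the other 5 libraries end in the consecutive numbers 6 to 10 and that of replicate 6 in 37, so its number falls outside the series in which both genotypes alternate. No pair of libraries agreed within sampling noise, with a chi-square of at least 148 per degree of freedom.

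**Figure D1:**
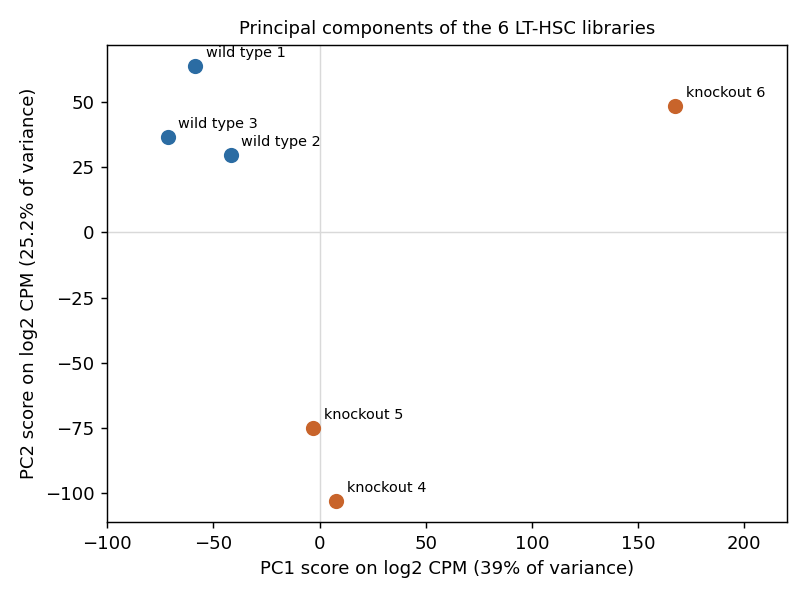
Scores of the 6 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; blue points are wild type and orange points are labelled knockout. Knockout replicate 6 lies at 167 on the first axis and the other libraries between -71.6 and 7.75.

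Procr and Ltb, both members of the fixed list of LT-HSC identity genes, rose in the libraries labelled knockout, and 16 genes fell, among them Cd48, F13a1, Chdh and Ect2. Of 37 fixed gene lists, camera with a preset correlation placed 8 higher and 14 lower, and 0 passed with an estimated correlation. Procr, the endothelial protein C receptor used to isolate stem cells, rose from 36.1 ± 2.03 to 164 ± 12.6 CPM (log2 fold change 2.18, SE 0.21), and Ltb, which encodes the cytokine lymphotoxin beta, rose from 49.4 ± 15.4 to 223 ± 21.8 CPM (2.18, SE 0.29). Cd48, a receptor of the SLAM family carried by committed progenitors, fell from 268 ± 69.9 to 13.1 ± 7.60 CPM (log2 fold change -4.36, SE 0.53). F13a1, the A chain of coagulation factor XIII and a transcript of monocytes, fell from 78.5 ± 21.5 to 0.185 ± 0.160 CPM. Chdh, choline dehydrogenase of mitochondria, averaged 18.2 ± 1.48 CPM in the wild-type libraries and had 0 counts in all 3 libraries labelled knockout, at least 663-fold lower against a floor of 3 counts over the group.

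In all, 2 genes were higher and 16 lower at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of 12603 tested, and all 18 had groups that did not overlap. These calls depend on the test. With limma-voom 0 genes passed, which ended all 18 calls (1775 genes at an unadjusted p below 0.05). With sample quality weights added 2 were higher and 2 lower, all 4 among the 18, and edgeR's test against a fold of 1.5 kept 7 of the 18. DESeq2 called 205 higher and 325 lower, edgeR's likelihood ratio test 144 and 288 and its exact test 133 and 271, each with all 18 among them. The share of called genes that was higher was 38.7%, 33.3% and 32.9% in these 3 tests against 11.1% in the quasi-likelihood test, so the excess of lower genes also varied with the test. Adjusted p-values of these genes lay between 0.0232 (Procr, F13a1) and 0.0496 (Ltb), with 0.042 for Cd48 and 0.0357 for Chdh in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Other genes of immune cells that fell were Clec12a, an inhibitory lectin of myeloid cells (107 ± 63.2 to 6.95 ± 1.78 CPM), Itgal, the alpha chain of the integrin LFA-1 (135 ± 33.3 to 16.4 ± 6.92 CPM), and Fcgr3, a receptor for IgG (42.8 ± 26.7 to 0.656 ± 0.414 CPM). Tifab, a regulator of innate immune signalling, fell from 25.4 ± 9.85 to 0.0923 ± 0.0652 CPM. Ccr2, the chemokine receptor of inflammatory monocytes, had 1895 counts in the wild-type libraries and 1 in those labelled knockout, a ratio of 2364 with a counting interval of 424 to 93425. The lymphoid transcription factor Ikzf3 had a ratio of 1536 (275 to 60706), the myeloid receptor Cd300lb 1190.1 (329 to 9834.5) and the potassium channel subunit Kcng1 829 (283 to 4022).

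Ect2, an exchange factor needed for cytokinesis, fell from 99.2 ± 11.4 to 23.6 ± 5.17 CPM, and Pkmyt1, a kinase that restrains entry into mitosis, from 114 ± 6.08 to 32.9 ± 4.37 CPM. Clec12a, Pkmyt1, Tpm4 and 4930427A07Rik lie outside the rule for named genes and were chosen after their values were seen. Tpm4, a tropomyosin of the actin skeleton, fell from 121 ± 25.8 to 25.6 ± 4.69 CPM, and the unnamed gene model 4930427A07Rik from 127 ± 15.2 to 29.8 ± 5.23 CPM. Procr lies on mm10 chromosome 2 (155751217 to 155755478, plus strand), Ltb on chromosome 17 (35194507 to 35196305, plus), Cd48 on chromosome 1 (171682055 to 171705257, plus) and Chdh on chromosome 14 (30009000 to 30040466, plus). Exons of Chdh, Pkmyt1, Tpm4 and F13a1 overlap opposite-strand exons of Cacna1d, Paqr4, Gm26586 and Gm30489 over 9.5%, 8.8%, 6.1% and 1.1% of their bases, and reads from such stretches cannot be told apart in libraries that do not mark strand. At an unadjusted p below 0.05 there were 1496 genes, 676 higher and 820 lower, where 630 would be expected by chance, and the groups did not overlap for 21.4% of genes, where chance gives 10%. No gene passed edgeR's quasi-likelihood test without any of wild-type replicates 1, 2 and 3 or without knockout replicate 4, with 1179, 1353, 1079 and 1465 genes at an unadjusted p below 0.05. Without knockout replicate 5, 0 were higher and 4 lower, and without replicate 6, which leaves the 5 consecutively numbered libraries, 2 were higher and 47 lower.

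**Figure D2:**
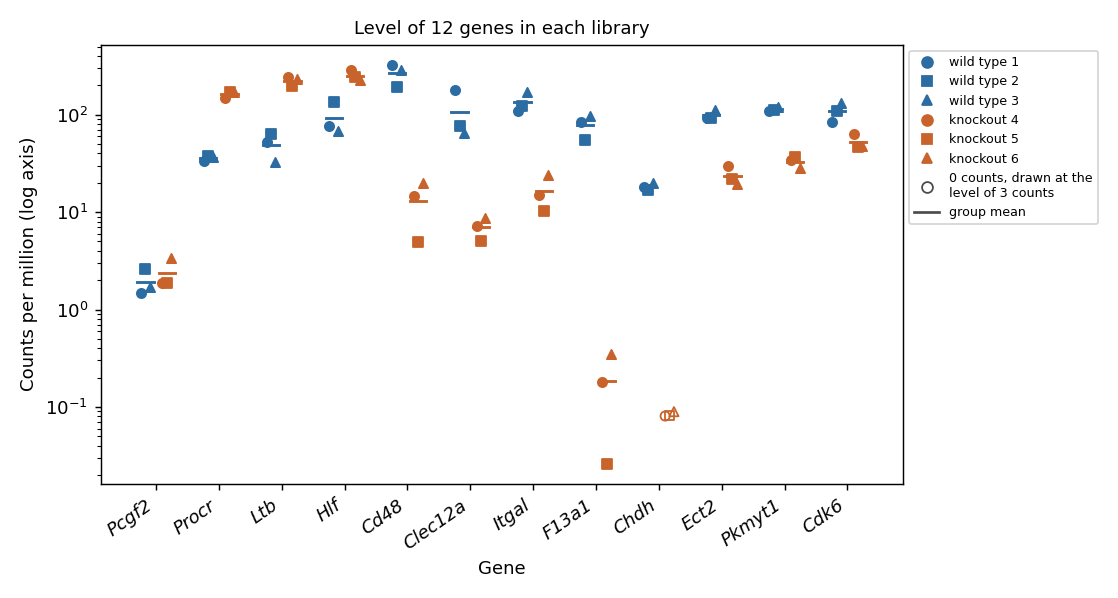
CPM on a log axis for 12 genes in each library, with wild type in blue, libraries labelled knockout in orange, a bar for each group mean and open symbols for libraries with 0 counts, drawn at the level of 3 counts. Procr and Ltb lie higher and Cd48, Clec12a, Itgal, F13a1, Chdh, Ect2 and Pkmyt1 lower in all 3 libraries labelled knockout, while Pcgf2 overlaps between the groups; Hlf and Cdk6 did not pass the test.

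Of 58 tested members of the list of LT-HSC identity genes, 53 were fitted higher, with a median log2 fold change of 0.94 (camera adjusted p = 1.39e-17 with the preset correlation, adjusted p = 0.188 with an estimated correlation). Of these 2 rose over all genes tested (Procr and Ltb) and 21 rose adjusted over the list alone. Hlf, a transcription factor of stem cells, averaged 92.7 ± 36.3 and 252 ± 33.9 CPM (log2 fold change 1.44, SE 0.30). Its adjusted p of 0.132 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes missed the threshold, as did those of Mecom (0.449), Meis1 (0.313), Gata2 (0.711) and Slamf1 (0.838). Hox and TALE homeobox genes, which pattern the embryo and act in stem cells, had 16 of 20 members higher (median 0.85, camera adjusted p = 0.00344, adjusted p = 0.236 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. Hoxa10 averaged 17.4 ± 6.41 and 54.5 ± 16.6 CPM, Hoxb7 0 and 2.26 ± 0.80 CPM, while Hoxb4, Hoxb5 and Hoxa9 had log2 fold changes of 1.00 (SE 1.48), 1.79 (SE 0.80) and -0.08 (SE 0.35). Without wild-type replicate 1 the median of the Hox list was 0.51, and without knockout replicate 5 it was 0.41.

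Of 66 interferon-stimulated genes 49 were fitted higher (median 0.54, camera adjusted p = 3.78e-06, adjusted p = 0.112 with an estimated correlation), including Ifitm3, a membrane protein that blocks virus entry (351 ± 82.4 and 819 ± 119 CPM), and Xaf1 (30.4 ± 5.10 and 60.3 ± 7.59 CPM). Of 19 genes of MHC class I and II, 13 were higher (median 0.38, camera adjusted p = 0.0153, adjusted p = 0.353 with an estimated correlation), among them H2-T23 (438 ± 63.9 and 870 ± 244 CPM) and H2-K1 (2456 ± 135 and 3715 ± 461 CPM). No member of either list passed over all genes or adjusted over the list alone. The MHC call was lost without wild-type replicate 3 (median 0.34) and with the length trend of each library removed (0.23).

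Of 38 tested members of the list of multipotent progenitor and lineage-primed genes, 30 were fitted lower (median -1.65, camera adjusted p = 4.43e-11, adjusted p = 0.124 with an estimated correlation). Cd48 fell over all genes tested, and 19 fell and 1 rose adjusted over the list alone. Dntt, the polymerase that diversifies antigen receptors, averaged 655 ± 470 and 7.06 ± 5.26 CPM, and Mpo, the peroxidase of granulocytes, 6247 ± 2521 and 156 ± 167 CPM. Both were chosen after their values were seen, and both missed the threshold over all genes (adjusted p = 0.0592 and 0.112, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mpo was the most abundant gene of wild-type replicates 1 and 3. The wild-type libraries thus held abundant transcripts of lineage-primed progenitors, and the purity of the sorts was not tested. The B lineage list had 14 of 16 members lower (median -2.33, camera adjusted p = 3.78e-06, adjusted p = 0.125 with an estimated correlation). In it 0 passed the test over all genes and 3 fell adjusted over the list alone. Ms4a1, the B-cell surface protein CD20, averaged 9.66 ± 4.10 and 0.0279 ± 0.0263 CPM, and Blnk 28.3 ± 6.51 and 5.63 ± 2.67 CPM. The list of T, NK and innate lymphoid cells had 17 of 21 members lower (median -2.31, camera adjusted p = 1.42e-05, adjusted p = 0.125 with an estimated correlation), 6 lower and 1 higher adjusted over the list alone, and 0 over all genes. Tcf7, a transcription factor of T-cell development, averaged 10.4 ± 5.08 CPM in the wild-type libraries and had 0 counts in those labelled knockout.

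The list of Monocytes, macrophages and dendritic cells had 17 of 27 members lower (median -0.65, camera adjusted p = 2.18e-05, adjusted p = 0.112 with an estimated correlation), of which F13a1 and Ccr2 fell over all genes and 7 fell adjusted over the list alone. That of Neutrophils and granulocyte precursors had 19 of 24 lower (median -0.58, camera adjusted p = 0.00225, adjusted p = 0.403 with an estimated correlation). In it 0 passed the test over all genes and 3 fell adjusted over the list alone. Ctsg, a protease of granules, averaged 374 ± 163 and 6.27 ± 4.79 CPM, and Ms4a3 104 ± 49.5 and 8.65 ± 5.04 CPM. That of Mast cells, basophils and eosinophils had 14 of 19 lower (median -1.74, camera adjusted p = 0.000694, adjusted p = 0.219 with an estimated correlation), 6 of them adjusted over the list alone and 0 over all genes, with Cpa3, a mast cell protease, at 83.0 ± 29.5 and 17.9 ± 6.44 CPM. The lists of Erythroid cells and of Megakaryocytes and platelets did not pass (medians 0.69 and 0.43, camera adjusted p = 0.248 and 0.106, adjusted p = 0.677 and 0.678 with an estimated correlation), and the erythroid median was -0.39 without knockout replicate 6. With the preset correlation, the erythroid list passed as higher without knockout replicate 5 (1.07), and the megakaryocyte list without wild-type replicate 2 (1.17) or knockout replicate 4 (0.59). Leaving out a library moved several of these medians. The monocyte median was -1.10 without wild-type replicate 3 and -1.37, -1.45 and -1.37 without knockout replicates 4, 5 and 6. The neutrophil median was -0.22 without wild-type replicate 1, which ended the call, -0.88 without wild-type replicate 3, -1.29 without knockout replicate 4 and -0.35 without replicate 6. Without knockout replicate 5 the median of T, NK and innate lymphoid cells was -7.60 and the mast cell median -2.81.

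Of 63 tested genes of G2, M phase and mitosis 62 were fitted lower (median -1.59, camera adjusted p = 3.32e-30, adjusted p = 0.159 with an estimated correlation). Ect2 fell over all genes tested, and 50 fell and 1 rose adjusted over the list alone. The last was Pttg1, or securin, which guards sister chromatid cohesion (34.4 ± 10.8 and 61.4 ± 10.2 CPM), named after its values were seen. All 60 genes of DNA replication were fitted lower (median -0.91, camera adjusted p = 2.94e-20, adjusted p = 0.112 with an estimated correlation), 32 of them adjusted over the list alone and 0 over all genes. The helicase gene Hells averaged 86.5 ± 16.6 and 28.9 ± 2.19 CPM, and the replication factor Mcm10 83.6 ± 23.2 and 21.9 ± 5.06 CPM. DNA repair genes had 44 of 54 lower (median -0.61, camera adjusted p = 3.78e-06, adjusted p = 0.223 with an estimated correlation). Of these 0 passed over all genes or adjusted over the list alone. Fancd2 averaged 36.7 ± 14.4 and 4.46 ± 3.61 CPM. The list of G1 cyclins and CDKs had 13 of 16 lower (median -0.64, camera adjusted p = 0.0328, adjusted p = 0.219 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all genes. The wild-type libraries also held more transcripts of lineage-primed progenitors. Whether these lists fell within stem cells or through a different mix of cells cannot be told from a single level per library.

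Cdk6, a kinase that sets the speed of exit from quiescence, averaged 109 ± 24.6 and 52.8 ± 9.78 CPM (log2 fold change -1.04, SE 0.27), and E2f1 108 ± 15.5 and 49.5 ± 8.84 CPM (-1.13, SE 0.25), with adjusted p = 0.189 and 0.144 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cdk4 had a log2 fold change of -0.21 (SE 0.23), Ccnd1 0.53 (SE 0.72), Myc -0.20 (SE 0.20) and Mycn 1.39 (SE 0.44), none past the threshold. Among inhibitors of these kinases, Cdkn1c averaged 12.2 ± 10.1 and 60.3 ± 10.9 CPM, Cdkn1a 71.4 ± 26.026 and 22.1 ± 6.70 CPM, and Cdkn2c had a log2 fold change of 0.30 (SE 0.37), also not past the threshold. Replication-dependent histones had 32 of 47 genes lower (median -0.51, camera adjusted p = 0.036, adjusted p = 0.403 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. The call for G1 cyclins and CDKs was lost without wild-type replicate 2 (median -0.58) or knockout replicates 4 (-0.27) and 5 (-0.49). The histone call was lost without wild-type replicate 1 (-0.50) or knockout replicates 4 (-0.46) and 5 (-0.52) and with a filter of at least 50 counts in 3 libraries (-0.28), and the median was -0.95 without replicate 6 and -0.96 with the length trend removed.

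The list of the unfolded protein and integrated stress responses had 28 of 37 members lower (median -0.52, camera adjusted p = 0.000456, adjusted p = 0.112 with an estimated correlation), with Atf6, a sensor of the endoplasmic reticulum, at 43.5 ± 10.8 and 13.5 ± 4.44 CPM, while Trib3, a target of that response, averaged 5.90 ± 2.14 and 28.1 ± 9.18 CPM. Of the list of Heat shock and chaperones 22 of 24 genes were lower (median -0.46, camera adjusted p = 0.00255, adjusted p = 0.361 with an estimated correlation), with Hsph1 at 161 ± 13.9 and 90.4 ± 18.7 CPM. The small chaperone Hspb8, at 0.0128 ± 0.0221 and 7.23 ± 3.20 CPM, was the single member past the test adjusted over the list alone, and it was higher. Genes of ribosome assembly and MYC-linked growth had 42 of 59 lower (median -0.27, camera adjusted p = 0.00193, adjusted p = 0.223 with an estimated correlation), including Nolc1 (269 ± 24.0 and 138 ± 38.6 CPM) and Cad (133 ± 71.4 and 38.8 ± 17.3 CPM). Of the list Antioxidant and NRF2 response 28 of 34 genes were higher (median 0.45, camera adjusted p = 0.000301, adjusted p = 0.32 with an estimated correlation), with Gsta4, a glutathione transferase, at 6.66 ± 2.82 and 30.1 ± 7.95 CPM. Gclc, the other member of this list that the rule names, was lower without overlap, with a log2 fold change of -0.85 (SE 0.25). Of the list Cholesterol and fatty acid synthesis 23 of 34 genes were higher (median 0.22, camera adjusted p = 0.0206, adjusted p = 0.236 with an estimated correlation), with Sqle at 79.0 ± 9.41 and 130 ± 21.5 CPM and Fdft1 at 31.5 ± 7.77 and 64.8 ± 21.4 CPM. Apart from Hspb8, 0 members of these lists passed over all genes or adjusted over the list alone. The heat shock call was lost without wild-type replicate 1 (median -0.21) and its median was -0.30 without knockout replicate 6. The cholesterol call was lost without wild-type replicate 1 (0.29) or knockout replicate 6 (0.13), with medians of 0.33 and 0.12 without wild-type replicates 2 and 3. The antioxidant median was 0.28 without wild-type replicate 3, 0.25 without knockout replicate 6 and 0.26 with the length trend removed.

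In the list Cytosolic ribosomal proteins 79 of 82 genes were fitted higher (median 0.73, camera adjusted p = 3.15e-18, adjusted p = 0.361 with an estimated correlation), with Rpl22l1 at 63.1 ± 13.1 and 108 ± 11.2 CPM and Rpl13 at 1078 ± 255 and 2238 ± 976 CPM. In the list Nuclear-encoded oxidative phosphorylation 72 of 77 genes were higher (median 0.42, camera adjusted p = 2.6e-07, adjusted p = 0.542 with an estimated correlation), with Uqcrh at 87.7 ± 28.8 and 182 ± 80.3 CPM. In both lists 0 members passed over all genes or adjusted over the list alone. These transcripts are short, with median exon lengths of 696 and 739 bases. Across all 12603 genes the log2 fold change declined with exon length (Spearman's rho -0.249 across genes, which are not independent replicates), from a median of 0.30 in the shortest of 5 equal length classes to -0.25 in the longest. By library, the shortest class deviated most in wild-type replicate 3 (median -0.45) and knockout replicate 6 (0.40). With the length trend removed the ribosomal median was 0.34 (camera adjusted p = 5.82e-09, adjusted p = 0.452 with an estimated correlation) and that of oxidative phosphorylation 0.05, which ended its call. Without knockout replicate 6 the medians were 0.34 and 0.15, and without wild-type replicate 3 the call for oxidative phosphorylation was lost (0.16).

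**Figure D3:**
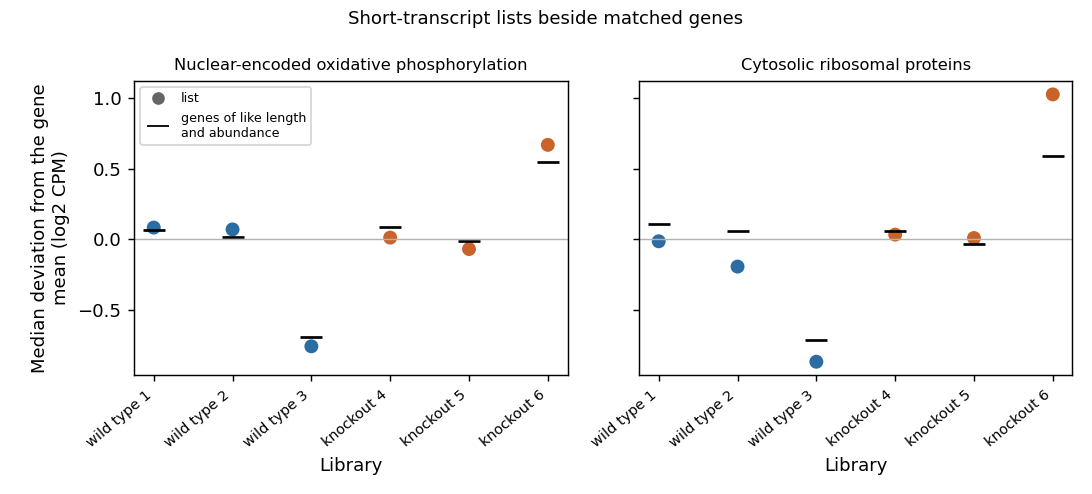
Median deviation of each library from the gene means, in log2 CPM, for the nuclear genes of oxidative phosphorylation and the cytosolic ribosomal protein genes (points, wild type in blue and libraries labelled knockout in orange), beside genes of like exon length and abundance (black bars). Wild-type replicate 3 lies at -0.76 and -0.87 and knockout replicate 6 at 0.67 and 1.02, with matched genes at -0.69 and -0.71 and at 0.55 and 0.59.

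No polycomb gene of the fixed lists passed the test. The lists of polycomb repressive complexes 1 and 2 did not pass (medians -0.09 over 39 genes and -0.18 over 13, camera adjusted p = 0.57 and 0.153), with 0 members past the test over all genes or adjusted over the list alone. Bmi1, the closest relative of Pcgf2, had a log2 fold change of -0.36 (SE 0.43), Ring1 0.27 (SE 0.36) and Rnf2 0.14 (SE 0.23). Ezh2, the methyltransferase of complex 2, averaged 136 ± 4.09 and 64.7 ± 28.7 CPM and Suz12 67.4 ± 11.8 and 28.0 ± 9.58 CPM, and Kdm2b 57.2 ± 21.5 and 28.7 ± 2.36 CPM, none past the threshold. Cdkn2a, a gene held silent by polycomb in many cells, was not listed among the deposited genes. The lists of quiescence genes, p53 targets, apoptosis regulators, glycolysis, autophagy, NF-kB, immediate-early genes, TGF-beta, Wnt and Notch, niche adhesion and endothelial cells did not pass either, with medians between -0.12 and 0.21 and camera adjusted p-values of 0.847, 0.107, 0.202, 0.0916, 0.153, 0.956, 0.303, 0.18, 0.797, 0.303 and 0.707 in that order. The niche list holds Itgal, which fell. The medians of Endothelial and stromal cells, Immediate-early genes and the Wnt and Notch pathway, at 0.01, -0.05 and -0.03, change sign with other library scalings. For the Wnt and Notch pathway the median and mean were negative and camera pointed up; for quiescence genes fry pointed down and the median was 0.08. Immediate-early genes passed as lower without knockout replicate 4 (-0.28) and as higher without replicate 6 (0.20). Autophagy and lysosome genes passed without knockout replicate 4 (0.21), and Quiescence-associated genes and CDK inhibitors without replicate 6 (0.02). These calls with a library left out used the preset correlation, and an estimated one was not run on them. With all 6 libraries the estimated correlation among immediate-early genes was 0.586. With the length trend removed, Glycolysis (median 0.21) and the TGF-beta and BMP pathway (0.52) passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.172 and 0.165 with an estimated correlation). Ldhb, a subunit of lactate dehydrogenase, averaged 60.1 ± 16.8 and 208 ± 24.7 CPM (adjusted p = 0.0592, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In total 22 of 37 lists passed camera with the preset correlation, 8 higher and 14 lower, and 0 with an estimated correlation.

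**Figure D4:**
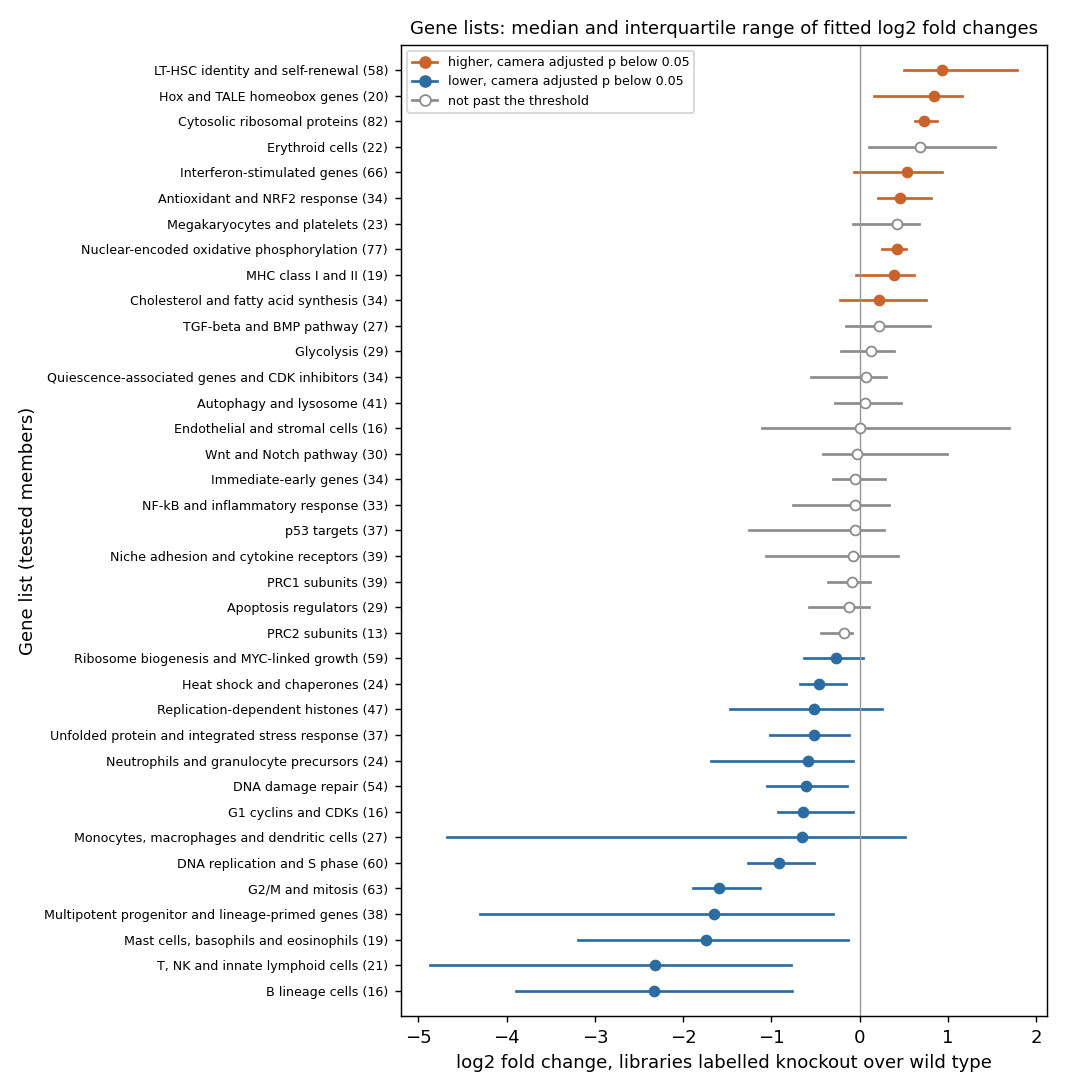
Median (points) and interquartile range (lines) of the log2 fold change, libraries labelled knockout over wild type, of the tested members of 37 gene lists, whose number stands beside each name. Filled points mark the 8 higher and 14 lower lists past the threshold of camera with the preset correlation, and open points the others.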

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

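The tests of transcript length, of a separate library batch, and of erythroid and megakaryocyte genes apart and by library were chosen only after the result was seen, and the other tests in this part were set before.

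In the authors' deposited table, 74 of the 109 genes that have 0 counts in all 6 libraries carry a log2 fold change beyond 1, up to 9.53, a signal in columns that the comparison above does not use. Counts of 0 in every library cannot give such values, so the fold changes in the authors' deposited table do not derive from these 6 count columns alone. The header names the groups as Cre+ and Cre- LT-HSCs, but the samples behind the fold changes are not given in the sources used here. The authors' deposited table has 230 genes at p below 0.05, where 697 would be expected by chance, and its adjusted column holds only whole numbers, 0 for Dntt and 1 for the other 13934 genes. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table gives 0.413 for Dntt, so the 0 there is not an adjusted p of 0. Across 12603 genes its log2 fold changes correlate with those fitted here at r = 0.422 (Spearman's rho 0.407, across genes, which are not independent replicates) and have the same sign for 65.1%, which is no check of either, with the samples of that fit unknown. All 18 genes called here have the same sign in the authors' deposited table, and 5 of them have p below 0.05 there. In the authors' deposited table the log2 fold change is 0.48 for Procr, -2.94 for Cd48, 0.13 for Hlf, 0.10 for Pcgf2 and -6.95 for Dntt.

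Genes of lineage-primed progenitors lay lower and stem-cell genes higher in the libraries labelled knockout, with both calls lost with an estimated correlation (adjusted p = 0.124 and 0.188). Against transcript length, the medians of the stem-cell and progenitor lists lay 2.76 apart with the length trend removed and 2.59 apart before. A loss of cells of every other lineage stays open: erythroid and megakaryocyte genes lay 1.53 (log2) above those of neutrophils, monocytes and B cells (two-sided permutation test over genes, p = 1e-05, the smallest it can give), which had been set to exclude it, but genes are not independent, the difference by library overlapped between the groups (-1.72 to 0.08 and -0.14 to 2.93), and without knockout replicate 6 the pooled difference was 1.23, still above the 1 set beforehand, with 1.49 for megakaryocyte and 0.67 for erythroid genes. A smaller share of lymphoid- and myeloid-primed progenitors inside the sort would give the median of -4.04 over 18 such genes (95% bootstrap interval over genes -5.60 to -1.94), but so would lower expression of these genes in stem cells, so these cannot be told apart from a single level per library. The neutrophil, monocyte, erythroid and megakaryocyte lists share members with the progenitor list, such as Mpo, Csf1r, Klf1 and Pf4. The 18 genes all come from it, so neither value is independent of the pattern. An effect of the genotype stays open and untested, since Pcgf2 was not lower and the gate of the sort is not given in the sources used here.

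Knockout replicate 6 stood apart from the other 5 libraries. Against wild-type RNA under its label, it lay at a median position of 0.863 (95% bootstrap interval 0.747 to 0.977) over the 49 genes called without it, where 0 is the wild-type mean and 1 the mean of knockout replicates 4 and 5. Its label number of 37 may mark a separate library batch: over 4958 genes of at least 50 CPM its mean correlation with knockout replicates 4 and 5 was 0.769, against 0.861 to 0.908 within genotypes among the others, but with a single library batch and animal cannot be told apart. The erythroid list median lay 1.63 (log2 CPM) above the highest other library, as a contribution of red cell precursors would give. Klf1 stood at 147 CPM against 11.978 to 82.6 CPM and Rhd at 119 against 2.64 to 10.3 CPM. Klf1, Rhd, Epor, Car1 and Alas2 lie outside the rule for named genes and were chosen after their values were seen. Of the members that the rule names, Car2 lay within the range of the other libraries. The other, Epb4.2, stood at 13.3 CPM against 0 to 10.8 CPM. Klf1, Epor, Car1 and Car2 are also in the progenitor list, Alas2 reached 15.2 CPM, and no hemoglobin gene was listed. Whether the sort removed red cell precursors is not given in the sources used here.

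Lists of ribosomal proteins and oxidative phosphorylation passed camera as higher in the libraries labelled knockout with the preset correlation but not with an estimated one (adjusted p = 0.361 and 0.542 with an estimated correlation), with 0 members past the test over all genes. For oxidative phosphorylation a candidate explanation is transcript length: the groups' mean library medians differed by 0.41, and by -0.02 once each gene was set against 20 genes of like exon length and abundance. For ribosomal proteins the difference was 0.71 before and 0.36 after this matching, with the 3 libraries labelled knockout at -0.02, 0.06 and 0.50 and the wild-type libraries at -0.12, -0.24 and -0.18. So length could account for part of it. Only a list's own members were left out of its matched genes. Members of the other list could thus serve as matched genes and shrink either difference. What was left after matching stays open, with genotype untested: it was 0.20 without knockout replicate 6, and all 3 libraries labelled knockout lay above all 3 wild-type libraries, where chance gives no overlap in 10%.

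The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 higher genes, 16 lower genes and 22 shifted lists, and 1 of the 10 splits, the real one, gave as many in each case. The highest of the other splits gave 0 higher genes, 0 lower genes and 16 lists.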

How the results depend on the processing

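Thinning all libraries to the shallowest total and removing the length trend were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the groups share no replicate numbers. All 18 called genes kept their direction under all alternatives that fit a model. DESeq2, the likelihood ratio test, the exact test, RLE factors, removal of the 20 most abundant genes and thinning called all 18. So did a fit without robust estimation, no count filter, a filter of at least 50 counts in 3 libraries and leaving out knockout replicate 6. Without any 1 of the other libraries, at most 2 of the 18 were called. Higher and lower genes numbered 205 and 325 with DESeq2, 144 and 288 with edgeR's likelihood ratio test, 133 and 271 with its exact test, 0 and 0 with limma-voom (1775 at an unadjusted p below 0.05), 2 and 2 with sample quality weights, 1 and 6 against a fold of 1.5, 3 and 25 without a count filter, 0 and 0 at an adjusted p below 0.01 (smallest 0.0232) and 14 and 51 below 0.1. The share that was higher was 11.1% in the edgeR quasi-likelihood test, 38.7% with DESeq2, 33.3% with the likelihood ratio test and 32.9% with the exact test. Thinning gave 2 and 19, the length trend removed 3 and 13, of which 14 were shared with the 18, and upper-quartile factors or total counts 2 and 11. Leaving out each library in turn gave 0 to 2 higher and 0 to 47 lower genes, a log2 fold change of Pcgf2 between -0.04 and 0.57 and 18 to 23 shifted lists. The Pcgf2 log2 fold change was -0.0379 without knockout replicate 6, the opposite sign. Fixed lists past the threshold numbered 0 with an estimated correlation and 11 with fry, 10 of them shared with the 22. The list gained with fry was Glycolysis, as higher (fry adjusted p = 0.0496). Among the lists lost with fry were LT-HSC identity genes (fry adjusted p = 0.0609), Hox and TALE homeobox genes, DNA damage repair and Cytosolic ribosomal proteins. A filter of at least 50 counts in 3 libraries left 21 lists, without Replication-dependent histones (median -0.28). Immediate-early genes passed as higher without knockout replicate 6 (median 0.20, camera adjusted p = 0.00527) and as lower without replicate 4 (-0.28, camera adjusted p = 0.00484), and as neither with all 6 libraries. Upper-quartile factors moved the median of all genes from -0.01 to 0.04. Beyond the leave-one-out losses, whose construction leaves fewer samples, and the thresholds, the cause was not tested. Simulated 2-fold changes were called in 6% of genes at this depth and spread.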

Other observations

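The list of imprinted genes, the test of it and the genes and lists given by library in this part were chosen only after the result was seen.

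No imprinted gene, a class that can be expressed from a single parental copy, passed the test over all genes. Ndn, a growth suppressor named necdin, averaged 5.78 ± 5.36 and 43.9 ± 3.58 CPM (log2 fold change 2.93, SE 0.66), Phlda2, which limits placental growth, 1.68 ± 0.52 and 13.3 ± 3.77 CPM, and Cdkn1c 12.2 ± 10.1 and 60.3 ± 10.9 CPM, with groups that did not overlap in each case. Their adjusted p-values of 0.144, 0.154 and 0.22 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment missed the threshold. Cd81, Tspan32 and Slc22a18, neighbours of Cdkn1c in an imprinted cluster, averaged 384 ± 98.5 and 689 ± 114, 435 ± 54.5 and 673 ± 97.9, and 9.13 ± 6.48 and 34.1 ± 18.9 CPM. In the other direction and also without overlap, Copg2 averaged 117 ± 22.9 and 77.4 ± 19.4 CPM, and Mcts2 had 129 counts in the wild-type libraries and 1 in those labelled knockout, a ratio of 161 with a counting interval of 28.4 to 6405. Of 29 tested imprinted genes 19 were fitted higher (median 0.63), and 8 were higher and 2 lower without overlap, where chance gives 10% in all and 21.4% of all tested genes did not overlap. Because the list was written after these values were seen, its test carries no weight: the unadjusted camera p was 0.00314 over all 29 (p = 0.0757 with an estimated correlation), 0.0249 without Ndn and Cdkn1c, and 0.351 without the 6 higher genes named here. Ndn and Cd81 are also members of the list of LT-HSC identity genes, and Ndn and Cdkn1c of that of quiescence genes.

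Some values varied widely between libraries of the same label. The median deviation of immediate-early genes from their means over the libraries was -1.45 (log2 CPM) in knockout replicate 6 and between -0.02 and 0.58 in the other libraries, and that of heat shock genes -0.57 against -0.17 to 0.45. Nr4a1 reached 1.16 CPM in replicate 6 and 146 to 511 CPM in the other libraries, Fos 1623.5 against 5436 to 9030.1 CPM, and the inducible chaperone Hspa1b 41.9 against 637 to 3727 CPM. Other members went the other way, with Klf10 at 174 CPM in replicate 6 against 83.4 to 126 CPM and the chaperone Hspb8 at 10.8 against 0 to 6.32 CPM. The median log2 CPM of the megakaryocyte list was 5.34 in wild-type replicate 2, 5.92 in knockout replicate 5 and 4.83 in knockout replicate 6, against 3.44 to 3.78 in the other libraries. Pf4, a platelet chemokine, stood at 354, 474 and 70.6 CPM in these 3 libraries and between 13.3 and 51.9 CPM in the others, and Gp9, a platelet receptor subunit, at 40.4, 62.0 and 57.2 against 9.29 to 23.6 CPM. Jchain, the joining chain of antibodies, was the most abundant gene of wild-type replicate 2 at 12982 CPM, against 47.3 to 1146 CPM in the other libraries.

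The X-inactivation transcript Xist, made in female cells, and Y-linked genes occurred together in 3 libraries. Xist had 731, 357 and 410 counts in wild-type replicates 1 and 2 and knockout replicate 4, and the Y-linked genes Ddx3y and Eif2s3y had 509 and 1524, 1233 and 1466, and 821 and 876 counts there. Both kinds of transcript together argue against RNA of a single mouse in each of these 3 libraries. Wild-type replicate 3 and knockout replicate 6 had 2136 and 1872 counts of Xist and at most 22 of each Y-linked gene. Knockout replicate 5 had 0 counts of Xist, which allows up to 3, and 1380 and 1777 of Ddx3y and Eif2s3y. Whether cells of several mice were pooled is not given in the sources used here, so n and SD throughout count libraries.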
